A study of Mus musculus with 34 samples.

How the data were processed

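RNA from CD4+ spleen cells of 5 inbred mouse strains (C57BL/6J, A/J, 129X1/SvJ, DBA/2J and Balb/c) was hybridised to Affymetrix arrays, 1 array per sample. The mice were female and 8 weeks old. CD4+ cells were taken with magnetic beads, kept in medium with fetal calf serum and divided into an unstimulated part (T0) and a part stimulated for 4 h (T1). The stimulus was phorbol 12-myristate 13-acetate (PMA) at 10 ng/ml with ionomycin at 1 uM, a pair of drugs that activate protein kinase C and raise cell calcium without the T cell receptor. The design text calls T0 the basal state, whereas the treatment protocol can be read as culture of both parts, so whether T0 cells spent those hours in culture is not given in the sources used here. Of the 34 arrays, A/J and C57BL/6J had 4 at each time and each of the other strains had 3. The labels call the replicates biological and number them within each strain.

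Per the labels, the authors processed the arrays with RMA, which corrects background, makes the arrays' distributions alike by quantile normalization and sums the probes of each probe set. The deposited values are log2 intensities, 1 per probe set and array. The version of RMA, the probe set definitions and any probe filter are not given in the sources used here. The values ran from 1.04 to 14.26 and the array medians from 5.28 to 5.39. Over the genes kept, correlations between arrays ran from 0.808 to 0.992, and no pair among the 561 pairs of arrays had more than 0.045% of probe sets at equal values.

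The table held 35556 probe sets. Of these, 21789 were listed with 1 gene symbol, 1621 with several and 12146 with none, a part that includes any control probe sets. Each of the 19938 genes was represented by its probe set with the highest mean over all arrays, taken from those with 1 symbol. More than 1 probe set was listed for 999 genes. A gene was kept when the highest of its 10 group means reached the median of all values (5.327), which kept 11413 genes and left out 8525. Group means under this limit are not shown to lie above background, so the sizes of differences that involve them are not exact. Among the 660 kept genes with several probe sets, 27 had probe sets called in opposite directions after stimulation. Gene names and the order of neighbouring genes came from the RefSeq gene table of assembly GRCm38.p6, in which 21698 of the 21789 gene identifiers were found. No positions are printed, since the build behind the array's own annotation is not given in the sources used here.

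Differences were tested with limma 3.58.1 in R 4.3.3. A single linear model with 10 groups (5 strains at T0 and T1) was fitted to all 34 arrays, so that each gene had 1 estimate of the spread, moderated across genes. The contrasts were T1 minus T0 in each strain and the mean of these 5 differences. Moderated F tests over the 5 strains were run at T0, at T1 and on the response (T1 minus T0, the interaction of strain and time). P values were adjusted by Benjamini-Hochberg over the genes kept, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are those of the moderated statistic, and group values are means ± SD over the group's arrays. The range of a gene over strains is the highest minus the lowest strain mean or strain response. For genes called by an F test, the strain whose mean lay farthest from the mean of the other 4 was recorded as standing apart, without a test. Shares of the sum of squares per gene were computed for time, strain, their interaction and the residual.

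Before the data were examined, 27 gene lists were fixed, covering cytokines, chemokines, homing receptors, immediate early transcription factors, the NF-kappaB pathway, feedback regulators, activation receptors, lineage transcription factors, quiescence, T cell receptor signalling, ribosome biogenesis, cholesterol synthesis, glycolysis, the interferon response, proliferation, p53 and apoptosis, heat shock, regulatory T cells, memory and effector T cells, the major histocompatibility complex, known strain variants, and markers of B cells, myeloid cells, neutrophils, CD8 T and NK cells, erythroid cells and platelets. They were tested with camera at its preset correlation of 0.01, and again with a correlation estimated from the data. The tests covered the mean stimulation, each strain against the other 4 at T0, and each strain's response against that of the other 4, adjusted within each of these families. Members called were also counted with p values adjusted over the list alone. An array's marker score is the mean log2 value of a list's members minus its mean over the 34 arrays. The rule for naming genes was fixed at the same time. It takes the 12 largest rises and 12 largest falls with the same sign in all 5 strains, the 20 largest ranges at T0, the next 10 at T1 and the 20 largest ranges of the response, passing over unnamed transcripts. It adds up to 4 members per list plus any that show an exception, and always Il2, Ifng, Tnf, Il4, Cd69, Cd4, Foxp3, H2-Ea and Nnt. Genes named outside this rule are marked as chosen after their values were seen, and 1 gene that the rule selects for the response is not reported here.

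Since the protocol says that sorted cells were divided, arrays of the same strain and number were taken as a pair from the same cells, 17 pairs in all. As a check, deviations from the group means were compared across genes within pairs. Their correlation ran from -0.0785 to 0.474 with a median of 0.258, it was over 0.1 in 14 of 17 pairs, and 13 arrays at T0 matched best the T1 array of their own number. The model has no block for pairs, and fits with such a block were alternatives. The labels give no day or batch. At T0, however, 3986 genes differed between arrays numbered 1 and 2 and arrays numbered 3 to 5, with strain as a term (2575 higher and 1411 lower in numbers 1 and 2, of which 26 differed by at least 1 log2), against 285 genes at T1. Counts within each of these number classes are therefore given beside the pooled ones.

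The steps were tested on simulated data of 11413 genes with known changes. For the mean stimulation, 98.5%, 100% and 100% of genes changed by 0.5, 1 and 2 log2 were recovered, for strain differences at T0 47.8%, 92.5% and 100%, and for differences in the response 19.4%, 80.6% and 97%. Of the unchanged genes, 15 of 11013, 6 of 11213 and 7 of 11213 were called. The simulated noise was independent between genes and arrays, without pairs or number classes, and only a small part of the genes was changed. These rates therefore need not hold for the data. For arrays, their number in each group limits the precision.

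Alternatives to each choice were run, and their effects are given in the closing section. They covered the filter, the gene level, 2 further normalizations, moderation with a trend, array weights, a stricter threshold, a test for a change beyond 1 log2 (limma's treat), a minimum range, replicate blocks, fits within 1 strain or time, and leaving out each array in turn. No array was left out of the values reported. Probe sets with no symbol or several symbols were left out of the comparisons, as were genes under the filter.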

Results

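The study measured gene expression in CD4+ spleen cells, mostly helper T cells, of 5 inbred mouse strains before and after 4 h with PMA and ionomycin. It held 34 arrays, with 4 per time for A/J and C57BL/6J and 3 per time for Balb/c, DBA/2J and 129X1/SvJ. Values are log2 intensities, and 11413 genes were compared. Time took the largest share of the variation per gene, with a median of 45.8%, against 9.9% for strain, 4.72% for their interaction and 26.3% for the residual. The leading principal component, which held 67.7% of the variance, separated T0 from T1. The array labelled Balb/c T1 replicate 2 lay apart from the other 2 arrays of its group, and the counts of called genes without it stand beside each comparison.

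The comparison of T1 with T0 asks what changed with stimulation, averaged over strains. If T0 cells were not kept in culture for those 4 h, an effect of culture cannot be told apart from that of the stimulus. The same limit holds for each later comparison of T1 with T0, including the strain responses. Cytokine genes were prominent among the largest rises. Il2 (probe set 10497878), the growth factor of T cells, rose by 5.94 log2 (SE 0.09, adjusted p = 5.38e-30), from strain means of 3.82 to 5.32 at T0 to 10.44 to 10.95 at T1. Its T0 means lay under the filter limit of 5.327, where background can make up much of a signal, so no fold is given. Ifng, the interferon that activates macrophages, rose by 5.26 (SE 0.09), Il3 by 5.11, the anti-inflammatory Il10 by 5.09, Lif by 4.31, Il17f by 4.24 and Il21 by 4.03. The chemokines Ccl4 and Ccl3 rose by 4.54 and 3.97, Gzmb, a protease of cytotoxic granules, by 4.00, Spry1, an inhibitor of MAP kinase signalling, by 4.19 and Fosb, a subunit of the AP-1 transcription factor, by 4.18. Each of these 12 genes was higher at T1 in 17 of 17 pairs, with adjusted p values up to 5.86e-21. Tnf rose by 2.82 (SE 0.07), the early activation marker Cd69 by 2.57 (SE 0.08) and Il4, the cytokine of type 2 helper cells, by 2.24 (SE 0.12). Il4 was higher at T1 in 15 of 17 pairs, Tnf and Cd69 in 17.

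Among the falls, Cd79b (probe set 10392142), a chain of the B cell receptor complex, changed by -4.21 (SE 0.12, adjusted p = 4.47e-24). S1pr1, the receptor that guides lymphocytes out of lymphoid organs, changed by -3.24, Cd55, which protects cells from complement, by -3.44, Rflnb by -3.74 and Cnp by -3.66. Cep97, a centrosome protein, changed by -3.13, Pcmtd2 by -3.07, Card6 by -3.05, Ms4a6c by -3.00, Tmem71 by -2.99, Traf3ip3 by -2.93 and Slfn1, of the Schlafen family, by -2.92. These 12 genes were lower at T1 in 17 of 17 pairs, with adjusted p values up to 1.55e-22. Cd4 itself changed by -0.86 (SE 0.06, lower in 17 of 17 pairs), Nnt, a mitochondrial transhydrogenase, by -0.87 (SE 0.06), and Foxp3, the transcription factor of regulatory T cells, by -0.26 (SE 0.09, adjusted p = 0.013). H2-Ea gave 0.24 (SE 0.12, adjusted p = 0.0702, or 0.0383 with strain and number as a block).

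Of the 26 cytokine genes kept, 24 rose, 1 fell and 1 was not called, with a median change of 2.30 (camera adjusted p = 1.17e-11). Lif, Il2, Ifng and Il3 had the largest statistics, Ltb changed by -2.02, and Osm gave 0.07 and was not called. All 26 immediate early transcription factors rose (median 1.89, adjusted p = 5.7e-15), among them Fos by 3.76, Egr2 by 3.24 and Myc by 3.22. Of 23 feedback regulators of MAP kinase, cytokine and calcium signalling, 20 rose and 2 fell (median 1.26, adjusted p = 1.48e-08). The phosphatase Dusp4 rose by 2.62 and Rgs16 by 2.51, while Dusp10 changed by -1.17 and Socs1 gave 0.12 and was not called. These 3 lists kept their calls with an estimated correlation (adjusted p = 0.00942 for each).

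Other lists were called at the preset correlation only. Of 26 activation receptors, 19 rose and 5 fell (median 1.04, adjusted p = 5.29e-06 at the preset and 0.083 with an estimated correlation). Slamf1 rose by 3.18, Cd200 by 2.78, the interleukin 2 receptor chain Il2ra by 2.68 and the inhibitory receptor Ctla4 by 1.87, while the interleukin 18 receptor Il18r1 changed by -1.93. Of 14 chemokines, 12 rose and 1 fell (median 1.52, adjusted p = 7.1e-05 and 0.247 with an estimated correlation), with Xcl1 at 3.32 and Ccl1 at 2.86. Of 16 homing receptors, 12 fell and 3 rose (median -0.75, adjusted p = 0.0361 and 0.281 with an estimated correlation). The integrin Itga4 changed by -2.24 and the selectin ligand Selplg by -1.94, while Ccr8 rose by 3.48. Of 21 quiescence genes, 16 fell and 3 rose (median -0.76, adjusted p = 0.00835 and 0.43 with an estimated correlation), with the interleukin 7 receptor Il7r at -2.78, Cnr2 at -2.64 and the transcription factor Klf3 at -2.46.

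Genes of growth and metabolism also moved. All 26 ribosome biogenesis genes rose (median 1.56, adjusted p = 3e-15 and 0.083 with an estimated correlation), with Rrp1b at 2.64 and the nucleolar GTPase Gnl3 at 2.41. Of 16 genes of cholesterol synthesis and uptake, 14 rose and 1 fell (median 0.84, adjusted p = 1.03e-05 and 0.281 with an estimated correlation), with Idi1 at 2.18 and Sqle at 1.95. Of 15 heat shock proteins and chaperones, 14 rose (median 0.95, adjusted p = 5.94e-07 and 0.083 with an estimated correlation), with the mitochondrial chaperone Hspd1 at 1.33. Of 15 glycolysis genes, 9 rose and 3 fell (median 0.20, adjusted p = 0.0299 and 0.43 with an estimated correlation). The hexokinase Hk2 rose by 2.68, and Pgk1 was not called (adjusted p = 0.948). The glycolysis call was also lost without the filter (adjusted p = 0.0553) and after quantile normalization (0.0539).

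Of 31 genes of the type I interferon response, 24 fell and 2 rose (median -0.64, adjusted p = 0.0297 and 0.694 with an estimated correlation). The sensor Ddx58 changed by -1.78, Ifit2 by -1.72 and Parp14 by -1.54, while Ifih1 rose by 0.93. Of 17 regulatory T cell genes, 8 rose and 5 fell (adjusted p = 0.0473 and 0.43 with an estimated correlation). Their median lay near 0 and moved by over 1.5 times without single arrays, so it is not given. Those that rose, such as Il2ra and Ctla4, are also known as activation genes of other T cells, and Foxp3 was among those that fell. The call of that list was lost without the filter (adjusted p = 0.102), after quantile normalization (0.0539) and with strain and number as a block (0.0695). It was also lost in 13 of the fits that left out 1 array, with adjusted p values up to 0.0542. Those arrays were A/J T0 replicates 4 and 5, A/J T1 replicate 2, Balb/c T0 replicate 4, Balb/c T1 replicate 1, C57BL/6J T0 replicates 2 and 4, C57BL/6J T1 replicates 1 and 3, DBA/2J T0 replicate 4, DBA/2J T1 replicate 2, 129X1/SvJ T0 replicate 4 and 129X1/SvJ T1 replicate 1. Markers of other cells fell as well. Of 16 B cell markers, 12 fell and 3 rose (median -1.57, adjusted p = 0.00987 and 0.43 with an estimated correlation), with Fcrla at -2.22 and the kinase Btk at -1.89, while Cr2 rose by 0.93. Of 10 neutrophil markers, 9 fell and 0 rose (median -1.54, adjusted p = 0.013 and 0.43 with an estimated correlation), with S100a9 at -1.94 and S100a8 at -1.82.

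The remaining lists were not called. The NF-kappaB pathway had 10 rises and 7 falls among 19 genes (adjusted p = 0.0537, and 0.0441, 0.0482 and 0.0494 without Balb/c T1 replicate 2, Balb/c T1 replicate 4 and C57BL/6J T0 replicate 1), with its inhibitor Nfkbid at 3.31. T cell receptor signalling had 4 rises and 14 falls among 21 (adjusted p = 0.101, and 0.00229 without the filter), with the adaptor Grap2 at -1.97. The major histocompatibility complex had 2 rises and 12 falls among 17 (adjusted p = 0.0537, 0.00262 without the filter and 0.0359 after quantile normalization), with Tapbp at -1.25. Its adjusted p was 0.0482 without Balb/c T1 replicate 4, 0.0494 and 0.0484 without C57BL/6J T0 replicates 1 and 4, and 0.0497 without 129X1/SvJ T0 replicate 1. Lineage transcription factors had 7 rises and 9 falls among 16 (adjusted p = 0.531), with Tbx21, the factor of type 1 helper cells, at 3.18 and Bcl6 at -1.17. Proliferation had 4 rises and 9 falls among 23 (adjusted p = 0.936), with Cdk6 at 2.02 and Mki67 at -0.09 and not called. The p53 and apoptosis list had 9 rises and 5 falls among 16 (adjusted p = 0.237), with Gadd45b at 2.67 and Sesn1 at -1.38. Memory and effector genes had 8 and 9 among 18 (0.464), with the adhesion receptor Cd44 at 1.55 and S100a10 at -1.06, and known strain variants 6 and 7 among 17 (0.783), with Slamf7 at 2.84 and Slamf6 at -1.89. Myeloid markers had 2 rises and 11 falls among 22 (adjusted p = 0.272, and 0.0164 without the filter), CD8 T and NK markers 6 and 5 among 12 (0.414), erythroid markers 1 and 0 among 9 (0.293), the rise being the transferrin receptor Tfrc (2.20), and platelet markers 0 and 1 among 3 (0.678). For the 12 lists not called, adjusted p values with an estimated correlation ran from 0.43 to 0.979. For each of the 27 lists, the numbers of rises and falls adjusted over the list alone were equal to these. In every list called, the median, the mean and the test had the same sign, whereas they differed for lineage factors, proliferation, memory genes and known strain variants.

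**Figure D1:**
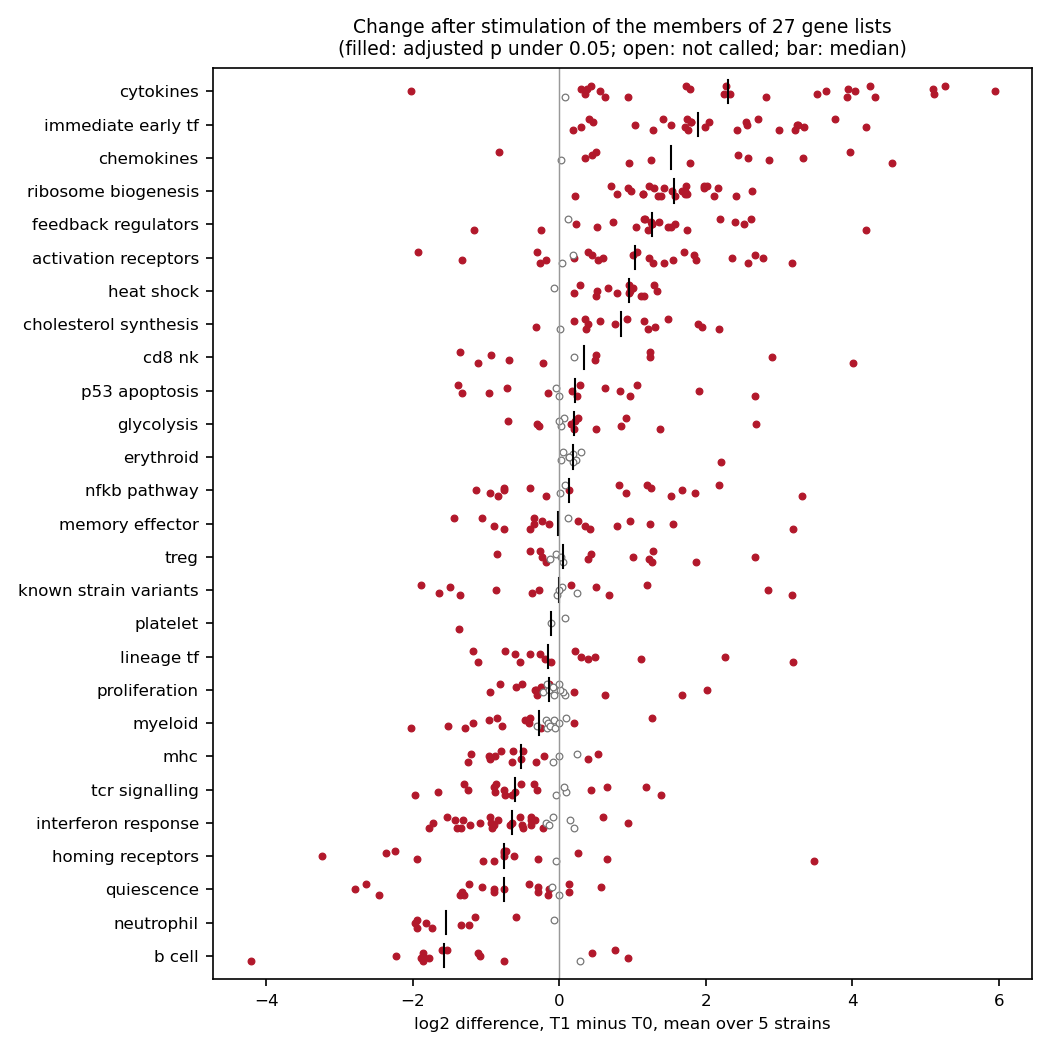
Each point is 1 member of a gene list, placed by its change after stimulation (log2, T1 minus T0, mean over 5 strains). Filled points passed an adjusted p of 0.05, open points did not, and bars are medians, from 2.30 for cytokines to -1.57 for B cell markers.

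Over all genes, 9392 of 11413 (82.3%) were called for the mean stimulation, 4113 higher and 5279 lower at T1, and 1804 of them changed by at least 1 log2 (711 up, 1093 down). Without the array labelled Balb/c T1 replicate 2 the count was 9372, of which 9217 were shared. Within numbers 1 and 2 the count was 8642, and within numbers 3 to 5 it was 7811. RMA sets the distributions of the arrays alike, so a rise or fall is relative to the other genes. Fewer calls rose than fell, but without the filter more did (8040 up, 5623 down).

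Within single strains, 6460 genes were called in A/J (2315 up, 4145 down), 6238 in Balb/c (2351 up, 3887 down), 7269 in C57BL/6J (2864 up, 4405 down), 6848 in DBA/2J (2715 up, 4133 down) and 6427 in 129X1/SvJ (2465 up, 3962 down). Groups of 4 arrays in A/J and C57BL/6J and of 3 in the others give unequal power, so these counts do not rank the strains. Il2 rose in every strain, by 5.42 in A/J, 5.73 in Balb/c, 5.41 in C57BL/6J, 6.74 in DBA/2J and 6.41 in 129X1/SvJ, and Tnf rose by 2.73 to 2.89. The same sign in all 5 strains was seen for 8418 of the genes called on average, and 4495 were called in all 5. Without the array labelled Balb/c T1 replicate 2 the Balb/c count was 5536, of which 5213 were shared. Within numbers 1 and 2 the counts were 5683 in A/J, 6025 in Balb/c, 6068 in C57BL/6J, 4734 in DBA/2J (1 array per time) and 5727 in 129X1/SvJ. Within numbers 3 to 5 they were 4748 in A/J, 5439 in C57BL/6J and 6078 in DBA/2J, and 2897 in Balb/c and 4143 in 129X1/SvJ with 1 array per time each.

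The comparison of strains at T0 asks which genes differed between unstimulated cells of the strains. H2-Ea (probe set 10450161), which encodes a class II histocompatibility chain, lay at 10.13 ± 0.35 in A/J (n = 4), 10.49 ± 0.24 in Balb/c (n = 3) and 11.65 ± 0.33 in DBA/2J (n = 3), against 4.59 ± 0.50 in C57BL/6J (n = 4) and 4.53 ± 0.19 in 129X1/SvJ (n = 3), a range of 7.11 log2 (limma F adjusted p = 1.71e-20). The low means lay under the filter limit, so no fold is given. Its level is textbook knowledge for mice, since strains of the b haplotype carry a deletion in this gene. Gdpd3 lay at 10.97 ± 0.22 in 129X1/SvJ (n = 3) against 4.38 to 4.86 in the other strains (limma adjusted p = 2.91e-25). Stab2 was high in DBA/2J (8.45 ± 0.14, limma, n = 3), as was Kcnma1, a potassium channel (7.48 ± 0.06). A further probe set of Kcnma1, with a mean of 3.24 near the bottom of the scale, showed a range of 0.04 (adjusted p = 0.97). Mid1 and Rab34 were high in Balb/c, at 9.99 ± 0.06 and 8.34 ± 0.31. Trim12a (9.41 ± 0.27) and Vmn2r96 (6.81 ± 0.51) were high in C57BL/6J, where the other strains had means of 3.82 to 3.95 and 2.63 to 2.89. Both belong to large gene families whose probes can share sequence.

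Il4 split the strains at T0. Its means were 10.61 ± 0.49 in A/J, 10.29 ± 0.24 in Balb/c and 9.72 ± 0.31 in C57BL/6J, against 6.89 ± 0.38 in DBA/2J and 6.85 ± 0.44 in 129X1/SvJ (range 3.76, 13.5-fold, adjusted p = 9.79e-14). Il2 and Ifng followed the same split at lower levels (adjusted p = 2.71e-07 and 4.25e-08), Il2 with all means under the filter limit. Genes of interferon-induced families varied too. Gbp2b had a range of 5.86, with 10.41 in A/J, a higher mean still in Balb/c and 5.14 in C57BL/6J. Ifi214 and Ifi209 had ranges of 4.70 and 4.06, with A/J lowest at 3.54 and 5.89. Ly6d, known from B cell precursors, had a range of 3.42, with 9.93 in DBA/2J and 6.51 in A/J. Nnt, in which C57BL/6J mice are known to carry a deletion, had its lowest mean at T0 in C57BL/6J, with a range of 0.57 (adjusted p = 0.0193). At T1 its mean was lowest in DBA/2J and it was not called (adjusted p = 0.135, or 0.00584 without Balb/c T1 replicate 2). The call at T0 was lost without Balb/c T0 replicate 2, C57BL/6J T0 replicate 3 or C57BL/6J T0 replicate 4 (adjusted p = 0.0551, 0.0764 and 0.0873). Foxp3 had a range of 0.71 (adjusted p = 0.0394), a call lost in 9 of the fits that left out 1 array, with adjusted p values up to 0.14. Those arrays, all at T0, were A/J replicates 1 and 2, Balb/c replicates 1 and 2, C57BL/6J replicates 2, 3 and 4, and DBA/2J replicates 3 and 4. Tnf and Cd4 were not called (ranges 0.40 and 0.35).

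Erythroid genes were among the largest ranges as well. Alas2, the enzyme that starts haem synthesis in red cell precursors, lay at 11.50 ± 0.28 in A/J and 5.80 ± 0.44 in 129X1/SvJ, a range of 5.70 (adjusted p = 2.55e-07). Slc4a1, the anion exchanger of red cells, had a range of 4.51 and Rhag one of 3.68. Ube2l6 (4.02), Gda (3.66) and Aldh1a1 (3.47) also had their highest mean in A/J and their lowest in 129X1/SvJ. All 9 erythroid markers kept were called, and all 9 adjusted over the list alone. Their score was 0.96 ± 0.47 in A/J (n = 4), 0.54 ± 0.41 in DBA/2J, 0.13 ± 1.08 in Balb/c, -0.73 ± 0.78 in C57BL/6J and -2.07 ± 0.46 in 129X1/SvJ. The list was called up in A/J (median 1.56, adjusted p = 1.59e-09 and 0.125 with an estimated correlation) and down in 129X1/SvJ (median -2.32, adjusted p = 4.28e-10 and 0.125 with an estimated correlation). The Balb/c spread is that of number 2, with erythroid scores of -1.04 at T0 and -1.03 at T1.

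Markers of other white cells also differed by strain. The neutrophil list was called up in A/J (median 1.15, adjusted p = 6.4e-10 and 0.125 with an estimated correlation) and down in C57BL/6J (median -1.50, adjusted p = 8.21e-14 and 0.106 with an estimated correlation). Ngp, a neutrophil granule protein, had a range of 3.57, and 8 of 10 markers were called, 8 adjusted over the list alone. The B cell list was called up in 129X1/SvJ (median 0.75, adjusted p = 1.17e-09 and 0.125 with an estimated correlation) and DBA/2J (median 0.58, adjusted p = 1.4e-08 and 0.125 with an estimated correlation), with 14 of 16 markers called, 14 adjusted over the list alone. Fcrla lay at 8.29 in 129X1/SvJ and 6.62 in A/J.

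**Figure D2:**
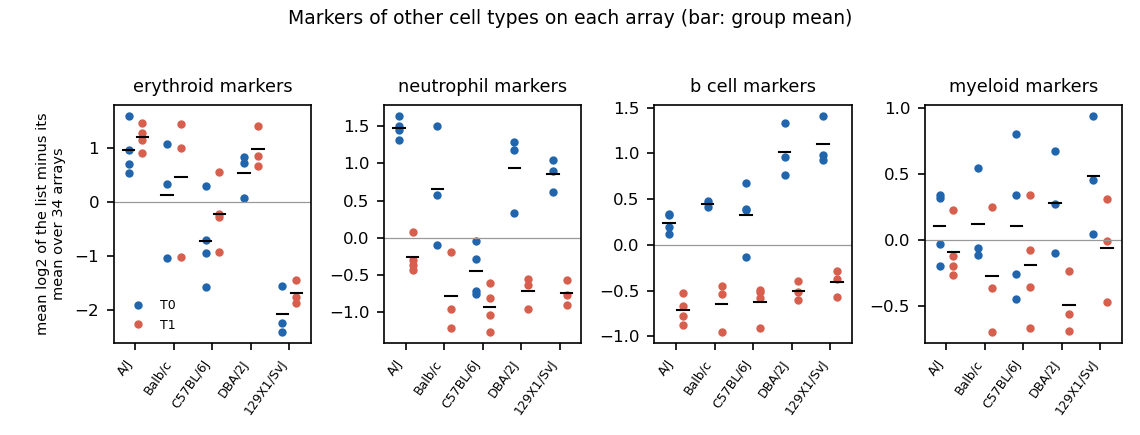
Each point is 1 array, placed by strain and time at its marker score (mean log2 value of the list minus its mean over 34 arrays), with bars at the group means. The erythroid mean at T0 ran from 0.96 in A/J to -2.07 in 129X1/SvJ, and B cell and neutrophil scores were lower at T1 than at T0 in each strain.

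Lists of T cell function differed as well at T0. The interferon response was up in C57BL/6J (median 0.47, adjusted p = 8.7e-10 and 0.286 with an estimated correlation; median 0.25 and adjusted p = 0.000645 without C57BL/6J T0 replicate 1) and down in DBA/2J (median -0.42, adjusted p = 1.66e-07 and 0.372 with an estimated correlation). The interferon score of C57BL/6J T0 replicate 1 was 1.52, against 0.27 to 0.66 on the other 3 arrays of that group. Of its 31 genes 22 were called between strains, 25 adjusted over the list alone. Oasl2 lay at 7.59 in C57BL/6J against 4.99 in Balb/c. Immediate early transcription factors were up in C57BL/6J (median 0.45, adjusted p = 4.28e-10 and 0.106 with an estimated correlation) and down in DBA/2J (median -0.21, adjusted p = 1.03e-07 and 0.125 with an estimated correlation). Feedback regulators were down in 129X1/SvJ (median -0.26, adjusted p = 1.03e-07 and 0.106 with an estimated correlation), with a median of -0.15 without 129X1/SvJ T0 replicate 2. By score, DBA/2J and 129X1/SvJ were lowest in both lists at T0. Immediate early scores were -1.32 and -1.28, against -0.998 to -0.721 in the other strains. Feedback scores were -0.92 and -0.976, against -0.533 to -0.414. Cytokine scores (-1.55 and -1.49, against -1.11 to -0.971) and activation receptor scores (-0.725 and -0.651, against -0.452 to -0.234) had the same split. Number class moved some of these lists at T0 as well. Across strains, 20 of 31 interferon genes were higher in numbers 1 and 2 (median 0.39), 18 of 22 myeloid markers were lower (median -0.70), 6 of 10 neutrophil markers were lower (median -0.51) and 7 of 9 erythroid markers were lower (median -0.80).

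In all, 2107 of 11413 genes (18.5%) were called between strains at T0, and 604 of them had a range of at least 1 log2. Without the array labelled Balb/c T1 replicate 2 the count was 2423. Fitted on the T0 arrays alone it was 2453, or 3195 with number as a block, and within numbers 1 and 2 and numbers 3 to 5 it was 976 and 927. 129X1/SvJ stood apart most often, for 684 of the genes called (32.5%, against 25.4% of all genes kept), then C57BL/6J for 500 (23.7%, against 21.2%), DBA/2J for 435 (20.6%, against 19.7%), A/J for 295 (14%, against 17.8%) and Balb/c for 193 (9.16%, against 15.8%). C57BL/6J was higher than the rest in 69% of its 500 genes, against 52.9% over all genes kept, and 129X1/SvJ in 43.6% of its 684, against 52%. Balb/c was higher in 63.7% of its genes, against 57.4%, A/J in 39.3%, against 39.5%, and DBA/2J in 46.9%, against 46.5%. The arrays are built on a reference sequence, so a strain's own sequence under the probes can lower its values. At T0 only 129X1/SvJ lay clearly below its share over all genes. At T1, DBA/2J (27.6%, against 40%) and 129X1/SvJ (51.1%, against 57.9%) did. Sequence under the probes was not tested as a cause.

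The comparison of strains at T1 asks the same after stimulation. H2-Ea kept its split (range 7.07, adjusted p = 1.77e-20), with 11.85 ± 0.18 in DBA/2J and 4.78 ± 0.31 in 129X1/SvJ (limma, n = 3 each). Gdpd3 remained high in 129X1/SvJ, at 9.50 ± 0.05 against 3.80 to 4.08. Of the 10 next largest ranges beyond the genes named at T0, 7 were those of genes known from red cells, namely Fech (4.16), Bpgm (4.10), Trim10 (3.44), Epb42 (3.34), Car2 (3.16), Kel (3.04) and Cldn13 (2.99), again with the highest mean in A/J and the lowest in 129X1/SvJ. The erythroid score at T1 was 1.20 ± 0.24 in A/J (n = 4) and -1.69 ± 0.23 in 129X1/SvJ (n = 3), and 7 of 9 erythroid markers were called, 8 adjusted over the list alone. Mki67, a marker of dividing cells, had a range of 3.11 with the same highest and lowest strain, and 17 of 23 proliferation genes were called, 20 adjusted over the list alone. Wls, which carries Wnt proteins to the cell surface, was high in 129X1/SvJ (8.82 ± 0.37) against 5.62 to 5.97. Ifi205 had a range of 3.37, with 8.38 in C57BL/6J and 5.01 in A/J.

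Cytokines differed at T1 more often in some genes than in others. Il3 lay at 9.26 in Balb/c, 9.03 in DBA/2J and 8.92 in C57BL/6J, against 7.20 in A/J and 7.14 in 129X1/SvJ (range 2.12, adjusted p = 3.33e-09). Gzmb had a range of 2.45 (adjusted p = 1.53e-06), with 10.00 in DBA/2J and 7.55 in A/J, and Ccl4 one of 1.16 (adjusted p = 3.24e-06). Il2, Ifng and Tnf were not called at T1 (ranges 0.51, 0.20 and 0.48, adjusted p = 0.361, 0.912 and 0.0929). Of the 26 cytokines 13 were called at T1, 14 adjusted over the list alone.

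In all, 3533 genes (31%) were called at T1, and 497 had a range of at least 1 log2. Without the array labelled Balb/c T1 replicate 2 the count was 4196, of which 3418 were shared. Fitted on the T1 arrays alone it was 2236, or 1878 with number as a block, and within numbers 1 and 2 and numbers 3 to 5 it was 776 and 1778. Both T0 and T1 calls were found for 1221 genes, where independent lists would share 652. The lists are not independent, since the arrays are taken as pairs and both tests use the same estimate of the spread per gene. At T1, 129X1/SvJ stood apart for 971 genes (27.5%, against 22.5% of all genes kept), A/J for 852 (24.1%, against 21.4%), DBA/2J for 842 (23.8%, against 23.5%), C57BL/6J for 625 (17.7%, against 17.1%) and Balb/c for 243 (6.88%, against 15.6%). DBA/2J was higher than the rest in 27.6% of its 842 genes, against 40% over all genes kept, and Balb/c in 65.4%, against 51.2%. The others were 56.2% in C57BL/6J, against 51.4%, 51.1% in 129X1/SvJ, against 57.9%, and 37.8% in A/J, against 37%. The standing-apart shares at T1 and for the response include the array labelled Balb/c T1 replicate 2, and none were computed without it. That array decided several Balb/c values at T1. There Kcnma1 lay at 10.83 against 3.26 and 2.87 on the other 2 Balb/c arrays, Trim12a at 7.24 against 3.83 and 3.79, and Rab34 at 5.32 against 7.72 and 7.68.

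**Figure D3:**
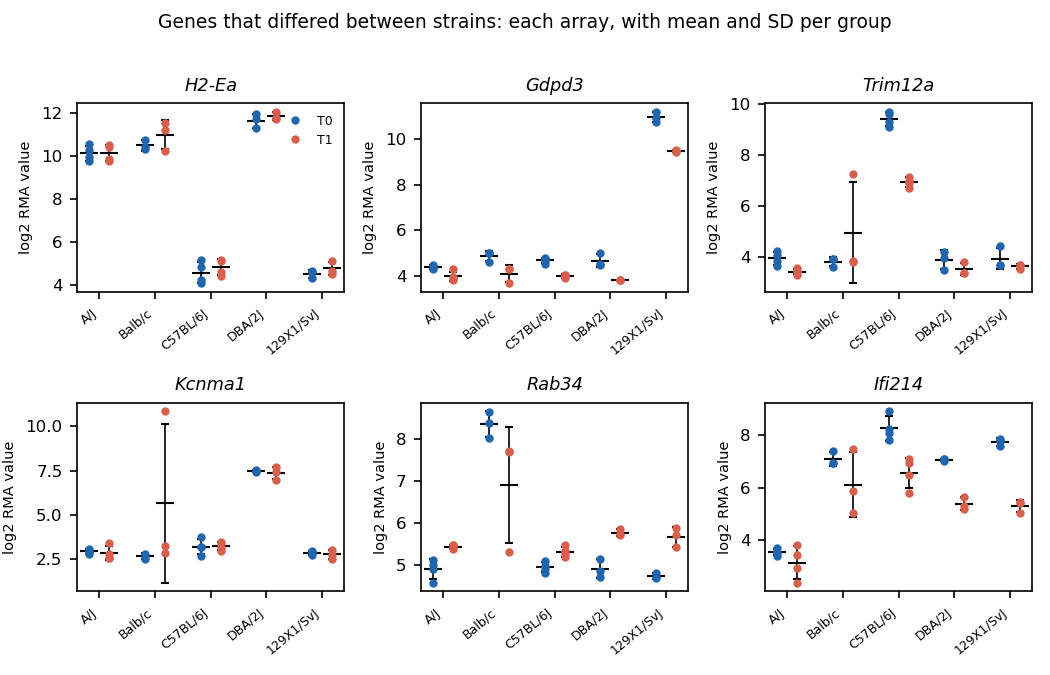
Points are log2 values of single arrays at T0 and T1 by strain, with horizontal bars at group means and error bars of 1 SD, for 6 genes that differed between strains. H2-Ea lay at 4.59 in C57BL/6J and 4.53 in 129X1/SvJ at T0 and above 10 in the others, and single Balb/c points at T1 lie far from their group for Trim12a, Kcnma1 and Rab34.

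The comparison of responses asks whether the strains differed in what stimulation changed, which is the question the series title names. Il4 (probe set 10385832) differed most. It rose by 4.90 in DBA/2J and 3.80 in 129X1/SvJ, by 1.18 in C57BL/6J and 1.13 in Balb/c, and gave 0.19 in A/J (adjusted p = 0.526 within A/J), a range of 4.71 (interaction adjusted p = 5.91e-10). At T1 its means lay between 10.65 and 11.79, so the difference in response was mostly one of the level at T0. Cish, a feedback inhibitor of cytokine signalling, rose by 2.89 in DBA/2J, 2.88 in 129X1/SvJ, 0.99 in C57BL/6J and 0.74 in A/J, and less in Balb/c (range 2.50, adjusted p = 3.37e-11). The chemokine Xcl1 rose by 4.78 in DBA/2J and 4.12 in 129X1/SvJ against 2.32 to 3.02 in the others (range 2.46, adjusted p = 4.42e-07). Il4ra, the receptor of interleukin 4, changed by -1.52 in Balb/c and by 0.79 in 129X1/SvJ (range 2.31, adjusted p = 3.05e-06). DBA/2J and 129X1/SvJ also rose more than the others in Il2 (range 1.33, adjusted p = 0.00493), Ifng (1.73, 6.33e-05) and Cd69 (1.30, 0.0083), and Cd4 fell most in DBA/2J (-1.56) and 129X1/SvJ (-1.11) (range 1.28, adjusted p = 0.00105). The T0 means of Il2, and that of Ifng in DBA/2J, lay under the filter limit, so the sizes of these differences in rise are not exact. Neither Il2 nor Ifng was called at T1, and both had their lowest T0 means in DBA/2J and 129X1/SvJ. Their differences in response were thus mostly ones of the level at T0. At T0 Cish lay at 6.66 in DBA/2J and 6.82 in 129X1/SvJ, against 8.38 to 9.07 in the others. Il4ra lay at 10.18 and 9.45, against 11.32 to 11.81. For both, the larger rises were in the strains with the lower level at T0. Gzmb rose by 5.35 in DBA/2J and 2.82 in A/J (range 2.53). Tnf and Foxp3 gave ranges of 0.16 and 0.47 (adjusted p = 0.982 and 0.79).

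Interferon-induced genes formed a further part. Gbp5, a guanylate binding protein, changed by -1.36 in C57BL/6J and by 1.89 in DBA/2J (range 3.25, adjusted p = 2.54e-10). Iigp1 changed by -2.73 in C57BL/6J and -0.10 in DBA/2J (range 2.63), and Ifi206 by -2.18 in C57BL/6J (range 2.44, or 1.88 without the array labelled Balb/c T1 replicate 2). Ifi202b rose by 4.16 in C57BL/6J and 1.85 in A/J (range 2.32). Cxcl10, a chemokine induced by interferon, had a range of 2.65 (adjusted p = 0.0292), a call that was lost in 7 of the fits that left out 1 array, with adjusted p values up to 0.073. Those arrays were A/J T0 replicate 2, A/J T1 replicates 4 and 5, C57BL/6J T0 replicates 3 and 4 and C57BL/6J T1 replicates 1 and 2. Gbp2b had a range of 3.30, which became 1.99 without the array labelled Balb/c T1 replicate 2. Klrb1f, a natural killer cell receptor, changed by -3.69 in Balb/c and least in 129X1/SvJ (range 2.97), and Ly6d by -2.67 in 129X1/SvJ and -0.21 in A/J (range 2.46), in step with B cell scores that were highest in 129X1/SvJ and DBA/2J at T0.

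In further genes the strains responded by different amounts. Vmn2r96 changed by -3.09 in C57BL/6J and was called in no other strain (range 3.44). Trim12a changed by -2.48 in C57BL/6J (range 3.62, or 2.48 without the array labelled Balb/c T1 replicate 2). Pls3, an actin bundling protein, changed by -2.42 in DBA/2J (range 2.56). Apol7c changed by -2.79 in C57BL/6J, -2.32 in 129X1/SvJ and -1.75 in DBA/2J, against -0.56 in A/J and -0.40 in Balb/c (range 2.39). Fam111a changed by -2.76 in 129X1/SvJ, -1.96 in DBA/2J, -1.71 in C57BL/6J, against -0.41 in A/J (range 2.35). In Balb/c it gave -0.82 (adjusted p = 0.048), and -0.23 without the array labelled Balb/c T1 replicate 2 (adjusted p = 0.565). Rab34 changed by -1.44 in Balb/c (range 2.37), and without that array by -0.64 (range 1.58).

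Among the lists, cytokines responded more in DBA/2J than in the other strains (median difference 0.28, adjusted p = 3.9e-07 and 0.181 with an estimated correlation) and less in A/J (median -0.26, adjusted p = 1.79e-05 and 0.256 with an estimated correlation). The interferon response fell further in C57BL/6J (median -0.55, adjusted p = 1.74e-10 and 0.338 with an estimated correlation, or a median of -0.18 and adjusted p = 5.02e-05 without C57BL/6J T0 replicate 1) and less in DBA/2J (median 0.40, adjusted p = 6.03e-06 and 0.506 with an estimated correlation). For these 2 lists the differences in response were mostly ones of the level at T0. The cytokine score at T1 ran from 1.12 to 1.34 over strains, while at T0 it was -1.55 in DBA/2J and -0.97 in A/J. The interferon score at T1 ran from -0.41 to -0.22, while at T0 it was 0.72 in C57BL/6J and -0.01 in DBA/2J. Activation receptors responded less in C57BL/6J (median -0.45, adjusted p = 1.74e-10 and 0.0875 with an estimated correlation), with 13 of 26 members called, 19 adjusted over the list alone. Their score at T0 was highest in C57BL/6J (-0.234, against -0.725 to -0.386 in the other strains). At T1 it was lowest there (0.369, against 0.446 to 0.584). The larger part of this difference in response was thus also one of the level at T0. Over all strains, 64 pairs of list and strain were called at T0 and 55 in the response at the preset correlation, and 0 of either with an estimated one, although 3 of 27 lists were called for stimulation in that way.

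In all, 790 genes (6.92%) were called for a difference in response, 335 of them with a range of at least 1 log2. Without the array labelled Balb/c T1 replicate 2 the count was 1185, of which 779 were shared, and with pairs as a random block it was 1386. Within numbers 1 and 2 and numbers 3 to 5 it was 111 and 175. Of the 790 genes, 723 were also called for the mean stimulation. Of the 886 genes called at T0 and not at T1, 237 (26.7%) had a called difference in response, as did 252 (10.9%) of the 2312 called at T1 and not at T0, so for most genes called at a single time the change between times was not itself shown. Among the 790 genes, DBA/2J stood apart for 240 (30.4%, against 24.1% of all genes kept), 129X1/SvJ for 204 (25.8%, against 21.7%), C57BL/6J for 196 (24.8%, against 19.5%), A/J for 86 (10.9%, against 17%) and Balb/c for 64 (8.1%, against 17.6%). DBA/2J responded higher than the rest in 31.2% of its genes, against 44.4% over all genes kept, and C57BL/6J in 26%, against 43.5%. A/J went the other way (70.9%, against 42.2%), while Balb/c (46.9%, against 50.4%) and 129X1/SvJ (56.4%, against 54.8%) lay nearer to their shares over all genes.

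**Figure D4:**
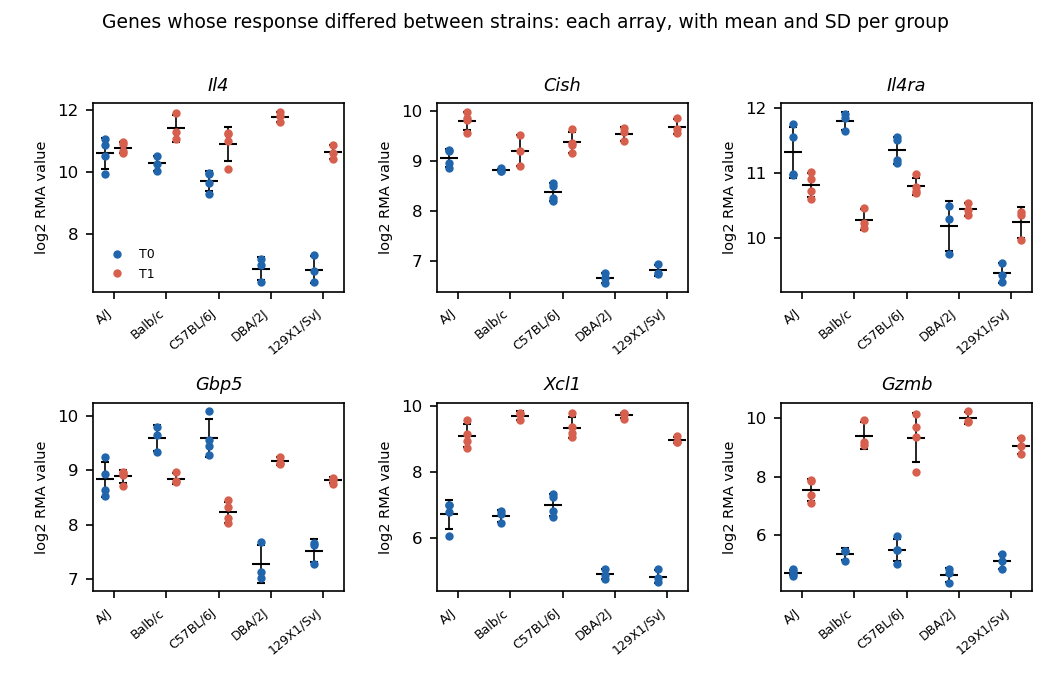
Points are log2 values of single arrays at T0 and T1 by strain, with horizontal bars at group means and error bars of 1 SD, for 6 genes whose response differed between strains. For Il4 the T0 means of DBA/2J (6.89) and 129X1/SvJ (6.85) lie below those of the other strains (9.72 to 10.61), while at T1 all means lie between 10.65 and 11.79.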

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

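Of the tests in this part, those of a swap, of a C57BL/6J label, of Il4 carried over from stimulated cells, of a probe variant in Il4 and of separate variants in erythroid genes were chosen only after the result was seen, as were Socs1 and the 8 genes named for 1 array.

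The difference in response between strains was itself tested, and 790 genes passed. Among the genes named for it, the range of the response over strains was 4.71 for Il4, 3.62 for Trim12a, 3.44 for Vmn2r96, 3.30 for Gbp2b, 3.25 for Gbp5, 2.97 for Klrb1f, 2.65 for Cxcl10, 2.63 for Iigp1, 2.56 for Pls3, 2.53 for Gzmb, 2.50 for Cish and 2.46 for both Xcl1 and Ly6d. It was 2.44 for Ifi206, 2.39 for Apol7c, 2.37 for Rab34, 2.35 for Fam111a, 2.32 for Ifi202b, 2.31 for Il4ra, 1.73 for Ifng, 1.33 for Il2, 1.30 for Cd69 and 1.28 for Cd4. Without the array labelled Balb/c T1 replicate 2 the range was 2.48 for Trim12a, 1.99 for Gbp2b, 1.88 for Ifi206 and 1.58 for Rab34. In the lists, 55 pairs of list and strain passed at the preset correlation.

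Single arrays lay far from the other 3 of their group in 16 of 288 groups of 4 (72 genes in 4 groups each), where chance gives about 1 in 20. On A/J T1 replicate 2, Il10 lay at 10.07 (others 10.47 to 10.48), Alas2 at 11.46 (11.86 to 11.91), Ube2l6 at 9.42 (9.96 to 10.07), Gda at 8.46 (9.04 to 9.12), Aldh1a1 at 8.19 (8.76 to 8.86), Fech at 8.08 (8.64 to 8.67) and Ifi205 at 3.95 (5.35 to 5.38). On A/J T1 replicate 4, Pcmtd2 lay at 6.62 (others 6.05 to 6.10), Tmem71 at 6.98 (6.46 to 6.50) and Klrb1f at 5.17 (4.59 to 4.66). On A/J T0 replicate 2, Ccl4 lay at 6.72 (others 6.87 to 6.90) and Cxcl10 at 7.01 (7.80 to 7.89). In C57BL/6J, Il17f lay at 8.67 on T1 replicate 1 (others 8.07 to 8.13), Ifi209 at 10.45 (9.71 to 9.83) and Tnf at 7.21 (7.62 to 7.64) on T0 replicate 1, and Mid1 at 8.38 on T0 replicate 3 (6.92 to 7.10).

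Probe sets outside the comparisons also changed with stimulation. Of 6663 probe sets with no listed gene that passed the filter, 374 were higher at T1 by at least 1 log2 and 513 lower, and of 891 with several genes, 53 were higher and 41 lower.

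The array labelled Balb/c T1 replicate 2 lies apart from its group. For a swap of 2 labels within the study, 0 of the other 33 arrays labelled another strain correlated best with a Balb/c array. The best match does not always give the strain, since Balb/c T0 replicate 4 correlated best with A/J T0 replicate 5 (0.9857). A swap is therefore not excluded by it. For a C57BL/6J array under a wrong label, 90.8% of 130 genes that separate Balb/c from C57BL/6J at T1 lay nearer to C57BL/6J, but 37 genes lay over 1 log2 from all 4 C57BL/6J T1 arrays (at most 24 for any of those 4), with H2-Ea at 10.24 against a C57BL/6J mean of 4.83. Against a mixture of RNA from the 5 strains, 8 genes lay over 1 log2 outside the range of the other 33 arrays (at most 4 for any of these), namely Cd160, Ehd3, Gpm6b, Il1r2, Il5, Kcnma1, Rmrp and Rnf7, and against a failed array, 83.6% of its 354 discordant genes were called between the other 4 strains, as were 35.8% of all genes. RNA of an animal of another background may be the source, which was not tested.

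The level of Il4 at T0 differs between strains. RNA carried over from stimulated cells would need a share of 86.9% in A/J, while the 12 genes with the largest rises allow a median of 0.503% (-5.27 to 5.45). A batch by replicate number that the strains share is argued against by the differences of A/J minus 129X1/SvJ. These were 3.83 within numbers 1 and 2 and 3.71 within numbers 3 to 5, the latter with a single 129X1/SvJ array. The numbers are given within each strain, so a difference in preparation that follows strain is not tested in this way. A sequence variant under the probes is argued against by T1 levels in DBA/2J and 129X1/SvJ that lay no lower than -0.146 from A/J. Cish, Socs1 and Il4ra had the same split at T0 (Cish 8.38 to 9.07 against 6.66 and 6.82). The strain itself and a difference in how the strains' cells were prepared both stay open as candidate explanations, since the labels give no dates.

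Erythroid markers differ between strains, with A/J high and 129X1/SvJ low. Red cell precursors or reticulocytes left among the sorted cells are a candidate explanation, because deviations of the 8 genes from their group means (the list without Tfrc, which activated T cells also express) correlated with a mean r of 0.788, where the highest of 10000 random lists was 0.482. Selection with CD4 beads would be expected to remove such cells, and Alas2 nonetheless lay at 11.50 in A/J at T0. A batch by replicate number is argued against by differences of A/J minus 129X1/SvJ of 3.37 and 2.94 within the number classes, the latter with a single 129X1/SvJ array. A difference in preparation that follows strain is not tested in this way, since the numbers are given within each strain. Separate variants in each gene stay open, since 129X1/SvJ being lowest for 7 of 8 genes is part of the pattern itself. Whether strains differ in such cells or in the yield of the sort stays open.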

How the results depend on the processing

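Chosen only after the data were seen were the fits to all probe sets, to each number class alone, with number class as a block and without both Balb/c arrays of number 2, the lists after quantile normalization and without each array, and the strain values of named genes without each array. For stimulation over all strains, no named gene and no list that was called changed direction, while for some list and strain pairs not named a median near 0 changed sign without 1 array. The balance of the mean stimulation turned, with 43.8% of calls higher as reported and 58.8% without the filter. In A/J and Balb/c, 56.6% and 54.8% of the genes that passed limma's treat, a test for a change beyond 1 log2, were higher, while among calls with a change of at least 1 log2 there were 643 up and 860 down, and 713 up and 1017 down. Counts of called genes that moved by over 1.5 times, with the causes not tested unless fewer arrays or genes were used, were as follows. For the mean stimulation, a stricter filter gave 5781 and all probe sets 15263 (10960 in C57BL/6J). Array weights gave 3406 at T0 and 1639 for the response, and an adjusted p under 0.01 gave 2045 at T1 and 390 for the response. Pairs as a random block gave 1386 for the response. Over the arrays of 1 time, number as a block gave 3195 at T0 and 1878 at T1 and number class as a block 3651 at T0, but the arrays of that time alone gave 2453 and 2236, against which these blocks moved no count by over 1.5 times. Treat gave 1234 for the mean, 800 in C57BL/6J, 592 in A/J, 873 in 129X1/SvJ, 1004 in DBA/2J and 642 in Balb/c, and calls with a range of at least 1 log2 were 604, 497 and 335 at T0, T1 and for the response. Numbers 1 and 2 alone gave 976, 776 and 111 for these last comparisons, and numbers 3 to 5 alone 927, 1778 and 175, with 2897 in Balb/c and 4143 in 129X1/SvJ. A group left with 1 array is assumed to vary like the others.

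With an estimated correlation, lists called went from 15 to 3 for stimulation, from 64 to 0 at T0 and from 55 to 0 for the response. Leaving out each array in turn gave 9230 to 9420 for the mean, 5952 to 6671 in A/J, 5536 to 6344 in Balb/c, 6693 to 7465 in C57BL/6J, 6144 to 7028 in DBA/2J, 5743 to 6626 in 129X1/SvJ, 1859 to 2423 at T0, 3023 to 4196 at T1 and 650 to 1185 for the response. The highest values at T0, at T1 and for the response were those without Balb/c T1 replicate 2, and without both Balb/c arrays of number 2 these were 2287, 4116 and 1122. H2-Ea gained a call for stimulation in 6 of 34 such fits (adjusted p down to 0.0106, without that same array). Among stimulation lists and named genes, strain and number as a block changed no other call than those of the regulatory T cell list (0.0695) and H2-Ea (0.0383), and it moved the list and strain pairs called for the response from 55 to 61. Over the fits without 1 array, lists called were 14 to 17 for stimulation, 62 to 69 at T0 and 51 to 59 for the response. The median of all genes after stimulation was -0.07 as reported, -0.02 after quantile normalization and -0.07 with each array centred on its median. Genes near the background are measured least well, and probe sets of low signal understate differences.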

Other observations

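The genes with opposite responses, the neighbouring genes given as examples and the counts of opposite responses without single arrays were chosen only after the values were seen, and the other tests in this part before.

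Stimulation moved 74 genes in opposite directions in different strains, with a called rise in at least 1 strain, a called fall in another and a called difference in response. There were 87 without the array labelled Balb/c T1 replicate 2, of which 65 were shared, and over the fits that left out 1 array 58 to 87. In 20 of the 74 (27 of the 87), DBA/2J and 129X1/SvJ had 1 sign and the other 3 strains the opposite one. No share over all genes was computed for this pattern. Socs1, an inhibitor of cytokine signalling, rose by 0.88 in DBA/2J and 1.21 in 129X1/SvJ and changed by -0.69 in Balb/c and -0.62 in C57BL/6J. Its T0 means were 7.12 in DBA/2J and 6.83 in 129X1/SvJ, against 8.565 to 8.757 in the other strains. The rises were thus in the strains with the lower level at T0, and opposite signs can reflect such differences in level. Irf1 rose by 0.69 in DBA/2J and 0.84 in 129X1/SvJ, changed by -0.52 in C57BL/6J and gave 0.46 in A/J (adjusted p = 0.0118, and 0.0782 without A/J T0 replicate 4).

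A hypothesis was that neighbouring genes vary together among strains, as inherited segments could make them do. Among 11400 genes placed in order, 569 pairs of next neighbours were both called at T0, where 388.5 are expected by chance. Of these, 157 (27.6%) had the same strain standing apart in the same direction, against a median of 12.13% and a highest value of 17.57% over 10000 random orders. Without pairs of like names, which might share probe sequence, it was 27.4% (138 of 504), against 12.1% and 17.86%. Examples are Rab34, Supt6 and Sdf2, higher in Balb/c, and Tnfaip3 and Ifngr1, higher in C57BL/6J. The random orders do not separate inherited segments from neighbours that are expressed together in the same cells, so the source of the likeness was not tested. The pairs alike also included Car1 and Car2, both erythroid markers, and Cd274 and Pdcd1lg2, both activation receptors.

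Other groupings of the same arrays were counted. For the mean stimulation, 1 of 100 draws, the real one, gave as many genes (9392, highest other 6104). In 50 draws that swap T0 and T1 within pairs, the highest was 8769. No redrawn grouping reached the real count, so chance alone is an unlikely source. The same holds for T0 (1 of 100, 2453 against 108), T1 (1 of 100, 2236 against 14) and the response (1 of 100, 1108 against 15), the last 3 fitted on the arrays or differences of that comparison alone. Redrawn strain labels do not test a difference in preparation that follows strain. In A/J and C57BL/6J, 1 of 35 splits, the real one, gave as many genes (6460 against 2521, and 7269 against 3425). The splits that part every pair, as the real one does, are too few for a share under 0.05 (highest other 2521 in A/J and 1549 in C57BL/6J). In Balb/c (6238, highest other 29), DBA/2J (6848, highest other 1) and 129X1/SvJ (6427, highest other 0), 10 splits are too few for a share under 0.05. Other splits that called many genes keep part of the time contrast.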
